A study of Mus with 8 samples.

How the data were processed

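Liver RNA was extracted with RNeasy and sequenced as mRNA libraries from 8 samples, 4 labelled DSS (libraries 15, 48, 49 and 50) and 4 labelled DSS with high-fat diet and alcohol (libraries 35, 45, 65 and 71). The study design says that mice received either a purified feed or a high-fat feed with alcohol after DSS; the feed of the DSS group is not stated outright in the labels. The labels give no batch, and no paired analysis was possible because the library numbers are not shared between the groups.

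The deposited table lists the authors' raw count per gene and library for 54532 genes, of which 20694 had more than 1 count in all. The submitters' processing notes name the builds GRCm38 and mm10; the aligner, the counting tool and the strand setting are not given in the sources used here, so reads shared between near-identical genes (Saa, Orm, Mup, Cyp2a, Gstm and globin genes) may have been split or dropped. The deposited FPKM values were checked to be the authors' counts divided by gene length and by an effective library size proportional to the DESeq2 size factor. The deposited log2 fold change is the authors' ratio of the diet-alcohol group over the DSS group. The deposited p-value and adjusted p-value are those of the authors' own comparison, whose tool is not stated; a DESeq2 rerun gave log2 fold changes within 3.1e-05 and p-values within 1.2e-05 of the deposited ones. The adjusted p was listed as 1 for 6018 genes that had a p-value, and p was missing for 103 genes.

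Total counts per library ran from 12502300 to 16967839, and counts of nuclear genes from 2722757 to 10947612; these depths cover counting error only. Genes were filtered with filterByExpr, which left 11729, normalized with TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit, R 4.3.3), with the adjusted p threshold at 0.05 (Benjamini-Hochberg). CPM values are TMM-normalized, with a prior count of 2 on the log2 scale. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), and again with a correlation estimated per list and with fry. The comparison, tests, 44 gene lists, alternatives and rule for naming genes were fixed before the data were examined. Single values were compared with an exact two-sided permutation test over the 70 assignments, whose smallest p is 0.0286. All 35 splits of the 8 libraries into 4 and 4 were refitted.

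The text names the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 CPM and no overlap between the groups, up to 4 members per list with the smallest p, and Tnf, Il6 and Il1b. Predicted and clone names, immunoglobulin and T cell receptor segments and pseudogenes were left out of the first part. Genes outside this rule are said to be chosen after their values were seen.

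The test was tried on simulated data in which 200 genes were changed, and 11428 genes were left to test after filtering. Of the changed genes that were tested, it recovered 7.81% of the 64 changed 2-fold, 65.1% of the 63 changed 4-fold and 92.2% of the 64 changed 8-fold. There were 4 false calls among 109. Changes of 2-fold would thus mostly be missed.

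Alternatives were RLE and upper-quartile normalization, DESeq2 1.42.0, limma-voom with and without sample weights, no filter, a filter of 1 CPM in 4 samples, a non-robust fit, an adjusted p threshold of 0.01, protein-coding genes only, limma on log2(FPKM + 1) and log2(FPKM + 0.1), glmTreat against a fold of 1.2, lists of 10 or more members, and leaving out each library. Leaving out the mitochondrial genes and using the mitochondrial share as a covariate were added after the data were seen.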

Results

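RNA from mouse liver was sequenced after colitis had been induced with dextran sulfate sodium (DSS), a polysaccharide given orally that injures the colonic epithelium. DSS was given at 2.5% and stopped on day 6. The labels place 4 libraries in a DSS group and 4 in a group that also received a high-fat diet and alcohol, here called the diet-alcohol group. Each library carries its own number in the labels, which do not say in so many words that each came from a separate mouse, so the p-values measure the spread between these libraries. Total counts per library ran from 12502300 to 16967839. Mitochondrially encoded transcripts took 55.8, 56.0, 69.9 and 79.1% of the counts in DSS libraries 15, 48, 49 and 50. They took 42.2, 35.5, 73.0 and 30.2% in diet-alcohol libraries 35, 45, 65 and 71. The group means were 65.2% ± 11.4 and 45.2% ± 19.2 (SD, n = 4 each; exact two-sided permutation p = 0.143). Nuclear genes therefore shared between 2722757 and 10947612 counts per library, and the groups did not separate on this measure either (exact permutation p = 0.143, n = 4 each). Library 35 listed 784 genes at 1 to 9 counts, against 4319 to 4987 in the other 7 libraries. It also stood apart as a whole, at 154 on the first principal component (50.6% of the variance) where the other 7 ran from -33.7 to -6.13. Its log2 CPM correlated with theirs at 0.762 to 0.819, against 0.875 to 0.945 among the other 7. Xist had no count in any library and Ddx3y, a Y-linked gene, had 245 to 712 counts, so all 8 libraries had the pattern of male tissue.

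**Figure D1:**
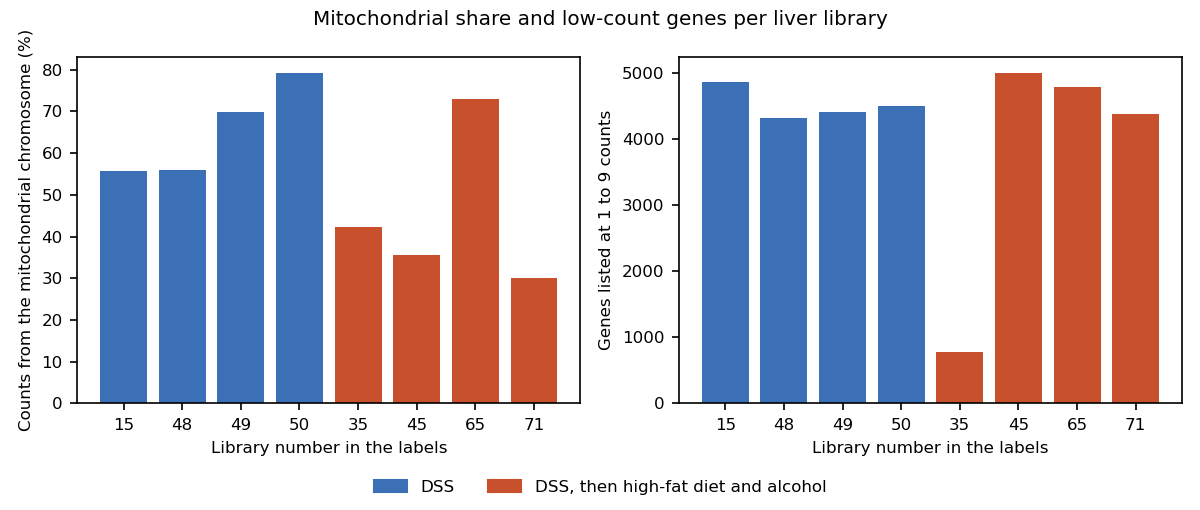
Share of counts from the mitochondrial chromosome (left, in percent) and number of genes listed at 1 to 9 counts (right) in each of the 8 liver libraries, coloured by group. The share runs from 30.2% in library 71 to 79.1% in library 50, and library 35 stands apart with 784 low-count genes.

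The comparison asks how the liver transcriptome of mice with DSS colitis differed when a high-fat diet and alcohol were added, in a study of liver injury that accompanies intestinal inflammation. Diet and alcohol were given together, so their contributions were not separable, and no mice without DSS were analysed here. In the diet-alcohol group, secreted acute-phase proteins were among the largest rises: Orm2 was 55.9-fold higher, Saa1 55.1-fold and Lcn2 53.2-fold. Of cholesterol synthesis and uptake genes 9 of 24 tested rose, a list whose call was lost with an estimated correlation (camera adjusted p = 0.126). Of the 7 neutrophil markers tested, of 20 listed, 5 rose. Of genes expressed mainly in male liver 10 of 18 fell, among them the major urinary protein gene Mup20 (22.1-fold lower). Outside that list Mup21 was 67.8-fold lower, and Scd1, which desaturates stearic acid, 14.5-fold.

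Of 11729 genes tested, 148 changed (edgeR quasi-likelihood F test, adjusted p under 0.05). Of these, 69 were higher and 79 lower in the diet-alcohol group, and 147 differed at least 2-fold. All 148 had no overlap between the 2 groups of 4 libraries; 8.77% of all tested genes had none, against 2.86% expected by chance. Single libraries moved the count by more than 1.5 times: it was 58 without DSS library 48, 74 without DSS 49, 77 without DSS 50, 83 without diet-alcohol library 45 and 308 without library 35. With the mitochondrial share as a covariate, a fit chosen after the data were seen, 55 genes passed.

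**Figure D2:**
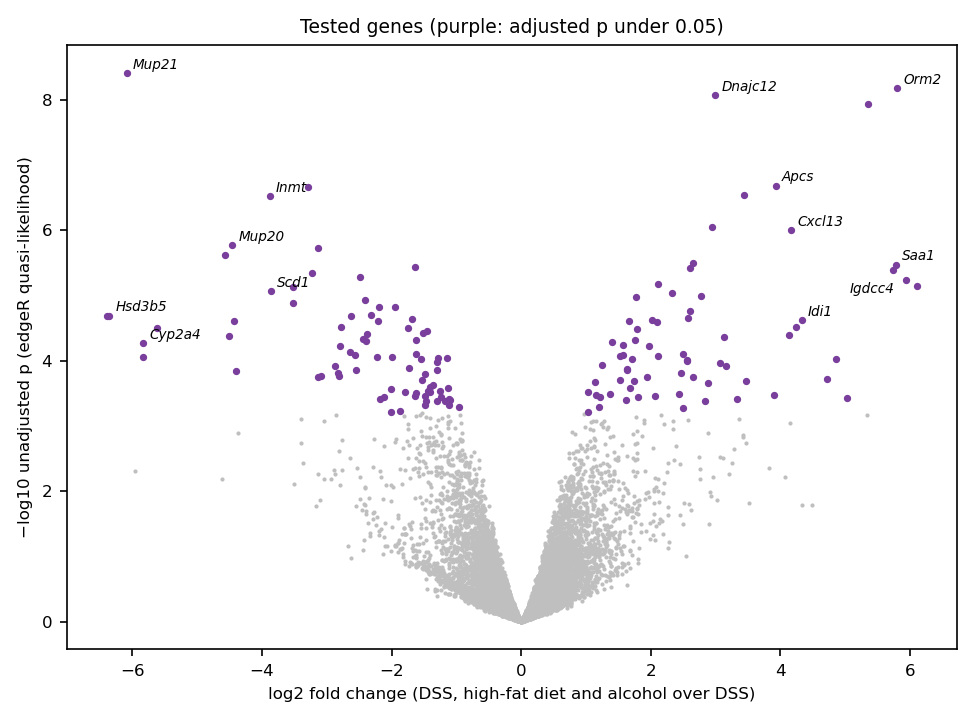
Log2 fold change (diet-alcohol over DSS) and −log10 of the unadjusted edgeR p-value of each of the 11729 tested genes, with the 148 genes past the adjusted threshold in purple. Mup21 lies at -6.08 and Orm2 at 5.81.

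The acute-phase response list holds plasma proteins and receptors that hepatocytes make under interleukin-6 and interleukin-1 signals. Of its 33 tested members, 18 rose, none fell and 15 did not pass the test; 30 were higher when adjusted over the list alone. The median log2 fold change was 1.98 (camera adjusted p = 5.1e-75), and the call held with an estimated correlation (adjusted p = 0.0013). Orm2 (ENSMUSG00000061540), an orosomucoid gene on chromosome 4 (63362449 to 63365878, GRCm38), went from 8.52 ± 3.52 to 481 ± 118 CPM (counts scaled to library size; SD, n = 4 each), with a log2 fold change of 5.81 ± 0.38 (SE; edgeR adjusted p = 3.4e-05). Apcs, which encodes serum amyloid P component, was 15.2-fold higher, at 761 ± 150.3 CPM in the diet-alcohol group (log2 fold change 3.93 ± 0.35, edgeR adjusted p = 0.00043). Orm3 and Orm1 rose by 5.35 and 3.43 on the log2 scale, and Saa2 and Saa1, which encode the major serum amyloid A proteins, by 5.94 and 5.78. Lcn2, the iron-scavenging lipocalin 2, went from 18.9 ± 16.5 to 1013 ± 569.6 CPM (log2 fold change 5.73 ± 0.69, edgeR adjusted p = 0.0027), or 6.56 without DSS 15. Orm1, Orm2 and Orm3, like Saa1 and Saa2, are near-identical copies whose reads the counting could have split between them. With the mitochondrial share as a covariate, the list's median was 1.96, Saa2 stood at 5.26 and Saa1 at 5.09.

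**Figure D3:**
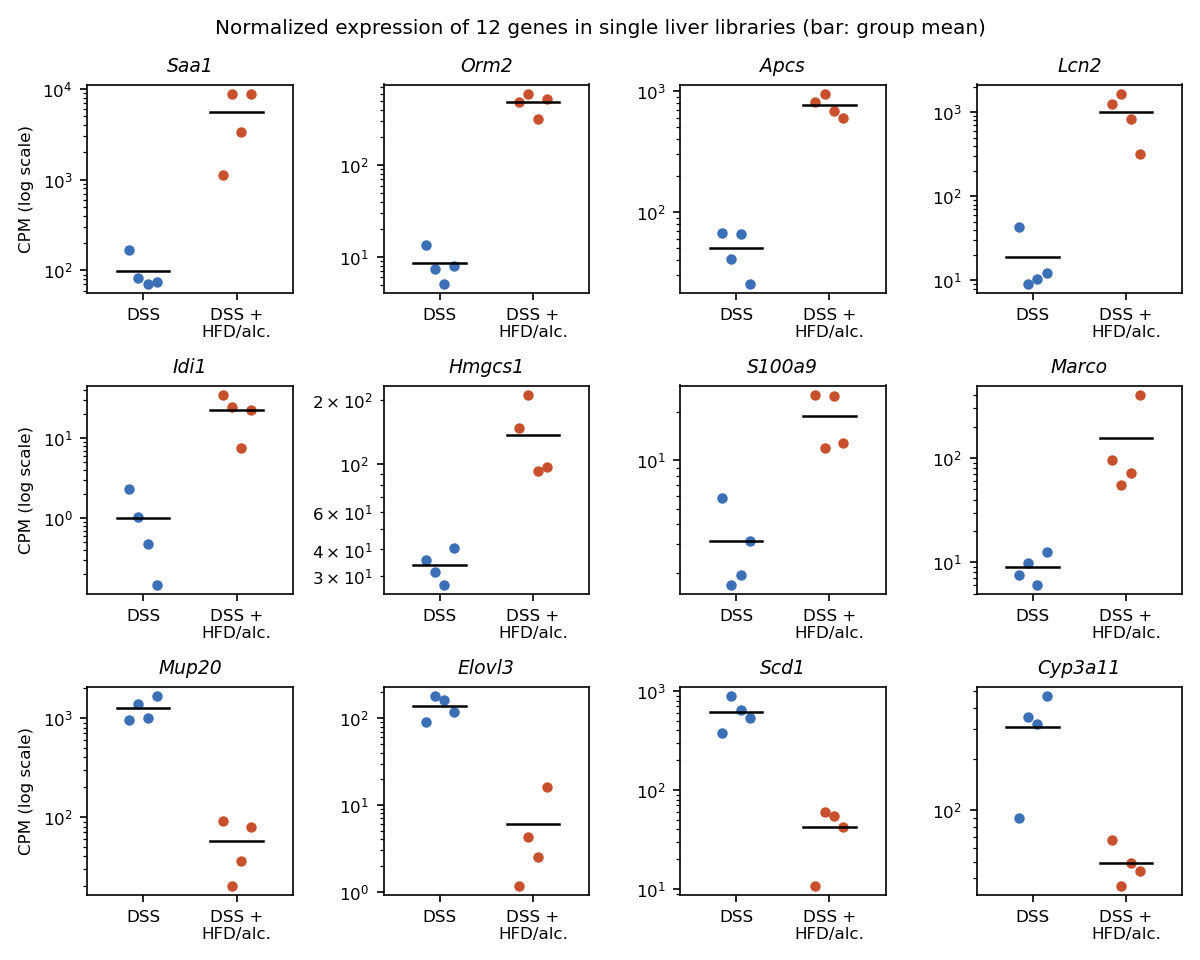
Normalized CPM, on a log scale, of 12 genes in the 8 libraries, with 1 point per library and a bar at each group's mean. The 4 diet-alcohol libraries lie above every DSS library for Saa1, Orm2, Apcs, Lcn2, Idi1, Hmgcs1, S100a9 and Marco, and below every DSS library for Mup20, Elovl3, Scd1 and Cyp3a11.

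Tested neutrophil markers were higher in the diet-alcohol group. The list holds 20 genes, of which the filter on low counts left 7 to test. Retnlg and Prtn3 had 9 and 21 counts in all DSS libraries together, so they passed that filter through their diet-alcohol counts. Of the 7 tested members of that list, 5 rose and none fell, with 6 higher when adjusted over the list alone (median log2 fold change 2.88, or 3.71 without DSS 15; camera adjusted p = 5.7e-14), and the call held with an estimated correlation (adjusted p = 0.012). Retnlg rose by 4.25 ± 0.63 on the log2 scale (edgeR adjusted p = 0.0076), from 0.202 ± 0.0857 to 3.94 ± 2.14 CPM. S100a9, a subunit of calprotectin, went from 3.13 ± 1.89 to 18.9 ± 7.44 CPM (log2 fold change 2.56, edgeR adjusted p = 0.015). Lrg1, which hepatocytes also express, rose by 1.56, and the granule protease gene Prtn3 by 4.71. Leaving out 1 DSS library (48, 49 or 50) ended the calls of S100a9 (edgeR adjusted p up to 0.070) and Lrg1 (up to 0.092). With limma-voom Retnlg lost its call (adjusted p = 0.335). The Prtn3 call was lost without any of DSS 15, 48, 49 and 50 or diet-alcohol 45 and 65 (up to 0.082). With the mitochondrial share as a covariate the list median was 2.92, and of the 5 members only Retnlg kept its call: S100a9 (edgeR adjusted p = 0.052), Prtn3 (0.074), Lrg1 (0.087) and S100a8 (0.091) lost theirs. S100a8 was named only after its values were seen. Prtn3 also lost it with limma-voom (0.519) and without a filter on low counts (0.155).

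Of 21 tested genes of the cytokine, chemokine and NF-kappaB list, 2 rose and none fell, both chemokine genes, and the same 2 passed when adjusted over the list alone (median 0.14, camera adjusted p = 0.233). Cxcl13, a B cell attractant, went from 2.55 ± 0.695 to 45.1 ± 27.5 CPM (log2 fold change 4.17 ± 0.44, edgeR adjusted p = 0.0012). Cxcl1, a neutrophil attractant, rose by 4.85 on the log2 scale (edgeR adjusted p = 0.014), with 35.1 CPM in library 65 and 4.53 to 5.76 in the other 3 diet-alcohol libraries; its call was lost without any 1 of the 4 DSS libraries (adjusted p up to 0.071), and its log2 fold change was 3.56 without library 65. That call was also lost with limma-voom (log2 fold change 4.08, adjusted p = 0.459) and without a filter on low counts (0.067). The list was called up with the mitochondrial share as a covariate (median 0.23, camera adjusted p = 0.0021), with Cxcl1 at 5.46. The study design names interleukin-6, tumour necrosis factor and interleukin-1 beta as measured proteins. Their liver transcripts were scarce: Il6 had 2 counts in library 65 and 0 in the other 7, and Tnf had 0 to 13 counts per library, so neither was tested. Il1b had 16 to 113 counts per library and a log2 fold change of -0.55 ± 0.51 (edgeR adjusted p = 0.759), or -1.10 without library 35 and -0.33 without library 45.

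Among Kupffer cell markers, Marco, a scavenger receptor of resident macrophages, rose by 4.13 ± 0.64 (edgeR adjusted p = 0.0089). C6, a complement gene that hepatocytes also express and that is also in the male-biased list, fell by 1.75. The other 12 of 14 members did not pass, and the list was not called (camera adjusted p = 0.089; 1 higher and 1 lower when adjusted over the list alone). Marco had 403 CPM in library 71 and 54.9 to 96.5 CPM in the other 3 diet-alcohol libraries, and its log2 fold change was 3.05 without library 71. The Kupffer list was called up with the mitochondrial share as a covariate (median 0.69, camera adjusted p = 0.00086), and so were monocyte and macrophage markers (0.74, 0.00027). In that fit Marco and C6, the only members past the test without it, lost their calls (edgeR adjusted p = 0.087 and 0.068), with Marco at 3.33. The Marco call was also lost without DSS 48, DSS 49 or diet-alcohol 35 (up to 0.061) and without a filter on low counts (0.105). None of 13 monocyte and macrophage markers passed (median 0.40, camera adjusted p = 0.070; 0.021 without library 35), nor when adjusted over the list alone. All 6 tested platelet and megakaryocyte genes had positive fold changes without passing singly, with 4 higher when adjusted over the list alone (median 1.46, camera adjusted p = 3.2e-05; adjusted p = 0.189 with an estimated correlation; median 0.96 with the mitochondrial share as a covariate). Pf4, platelet factor 4, had a log2 fold change of 1.79 (edgeR adjusted p = 0.071). All 7 tested genes of antigen presentation by MHC class II had negative values, none past the test over all genes or over the list alone (median -1.15, camera adjusted p = 0.0012; adjusted p = 0.446 with an estimated correlation). Their median was -2.56 without library 65, and H2-Eb1 stood at -1.47, or -3.24 without library 65, where it passed (edgeR adjusted p = 0.0046). The mitochondrial covariate took the MHC class II median to -0.57 and ended the list's call (camera adjusted p = 0.087), with H2-Eb1 at -0.76; with limma-voom H2-Eb1 stood at -2.64. B and plasma cell markers had a median of -0.58, with 0 of 7 past either adjustment (camera adjusted p = 0.048; adjusted p = 0.577 with an estimated correlation). That list's call held only without library 65 among the fits leaving out 1 library (median -2.02; camera adjusted p up to 0.497 in the other 7). Its median was 0.05 without library 45, -0.01 without DSS 50 and -0.30 without library 71. It was -0.06 with the mitochondrial covariate, which ended the call (camera adjusted p = 0.729). None of 3 tested T and NK cell markers passed over all genes or over the list alone, too few for a list test.

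In the interferon response list, Bst2, a membrane protein induced by interferon, fell by 1.63 (edgeR adjusted p = 0.013) and 32 of 33 members did not pass; 1 was lower when adjusted over the list alone. The median was -0.46 (camera adjusted p = 0.00027; adjusted p = 0.578 with an estimated correlation), and -0.23 without library 35, which ended the list's call (adjusted p = 0.066). It was -0.25 without DSS 50 and -0.76 without diet-alcohol 71. The Bst2 call was lost without DSS 48, 49 or 50 or diet-alcohol 45 (edgeR adjusted p up to 0.065), and with the mitochondrial covariate (0.091).

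Genes of cholesterol synthesis and uptake were higher in the diet-alcohol group: 9 of 24 tested members rose, none fell and 15 did not pass, and 17 were higher when adjusted over the list alone. The median log2 fold change was 1.44 (camera adjusted p = 2e-20; adjusted p = 0.126 with an estimated correlation), and it was 0.85 with the mitochondrial share as a covariate. Idi1, which isomerizes isopentenyl diphosphate, rose by 4.33 ± 0.63 (edgeR adjusted p = 0.0066), from 0.997 ± 0.950 to 22.3 ± 11.2 CPM. Msmo1, a sterol-C4 methyl oxidase, rose by 2.57 ± 0.37 (edgeR adjusted p = 0.0066) to 29.1 ± 12.5 CPM. Hmgcs1, which makes HMG-CoA in the cytosol, rose by 2.02 and Fdft1, squalene synthase, by 1.66. The log2 fold change of Idi1 was 5.13 without DSS 15, and its call was lost with limma-voom (adjusted p = 0.197). With the mitochondrial share as a covariate Idi1 fell to 3.36 (edgeR adjusted p = 0.025) and Msmo1 to 1.90, and Hmgcs1 and Fdft1 lost their calls (0.076 and 0.068).

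In the list of fatty acid and triglyceride synthesis 2 of 23 tested members fell, Scd1 and Elovl5, none rose, and 7 were lower when adjusted over the list alone (median -0.37, camera adjusted p = 6.3e-05; adjusted p = 0.181 with an estimated correlation). Scd1 went from 609 ± 217 to 42.0 ± 22.0 CPM (log2 fold change -3.86 ± 0.50, edgeR adjusted p = 0.0040), and Elovl5, a fatty acid elongase, fell by 1.49 (edgeR adjusted p = 0.020). In the list of fatty acid oxidation and PPAR-alpha targets 6 of 34 members fell and none rose, with 10 lower when adjusted over the list alone (median -0.27, camera adjusted p = 4.9e-07; adjusted p = 0.436 with an estimated correlation). The median was -0.17 without DSS 15 and -0.67 with the mitochondrial covariate. Acsl1, which activates long-chain fatty acids, fell by 1.94 ± 0.27 (edgeR adjusted p = 0.0056). Acaa1b, a peroxisomal thiolase, fell by 2.81 and Cyp4a10, an omega-hydroxylase, by 1.79. The call of Elovl5 was lost without DSS 48 or 49 or diet-alcohol 45 or 65 (edgeR adjusted p up to 0.098), and that of Acaa1b without DSS 48 or 50 or diet-alcohol 45 or 71 (up to 0.069). That of Cyp4a10 was lost without any library but 35 and 71 (up to 0.12) and with the mitochondrial covariate (0.184), and that of Acaa1b also without a filter on low counts (0.068). Acaa1b stood at -3.80 with the covariate.

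In the lipoprotein list 2 of 19 members fell, Apoa5 and the hepatic lipase gene Lipc (log2 fold change -1.41 each), none rose and 5 were lower when adjusted over the list alone (median -0.82, camera adjusted p = 1.5e-07; adjusted p = 0.163 with an estimated correlation). Without DSS 48, 49 or 50 or diet-alcohol 45 or 65 both genes lost their calls (edgeR adjusted p up to 0.12 for Apoa5 and 0.13 for Lipc), and also with the mitochondrial covariate (0.079 and 0.211). Of 23 bile acid genes, Slco1a1, an organic anion transporter, fell by 3.52 ± 0.48 (edgeR adjusted p = 0.0051), from 48.9 ± 21.5 to 4.39 ± 3.19 CPM, and 22 did not pass. Slco1a1 is also in the male-biased list, and its log2 fold change was -4.12 without library 65. When adjusted over the list alone 2 were lower (median -0.48, camera adjusted p = 0.0012; adjusted p = 0.188 with an estimated correlation), and the median was -0.76 without DSS 15 and -0.29 with the mitochondrial covariate. None of 19 genes of lipid droplets and fat storage passed; when adjusted over the list alone 1 was higher and 2 were lower (median -0.33, camera adjusted p = 0.235). That list was called down with the mitochondrial share as a covariate (median -0.64, camera adjusted p = 0.0047). Hsd17b11, a lipid droplet dehydrogenase, stood at -1.10 and Pparg at 1.41.

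Male-biased liver genes were lower in the diet-alcohol group. Of 18 tested members 10 fell, none rose and 8 did not pass, with 15 lower when adjusted over the list alone. Among those that fell were Slco1a1, C6 and Cyp2f2, which are counted again in the bile acid, Kupffer, periportal and P450 lists. The median log2 fold change was -2.54 (camera adjusted p = 3.5e-35), and the call held with an estimated correlation (adjusted p = 0.018). Mup20 (ENSMUSG00000078672, chromosome 4, 62050234 to 62054158, GRCm38), a pheromone-binding urinary protein also known as darcin, had a log2 fold change of -4.46 ± 0.49 (edgeR adjusted p = 0.0018) and went from 1257 ± 336 to 57.0 ± 34.4 CPM. Selenbp2 went from 62.7 ± 30.1 to 2.76 ± 1.94 CPM (log2 fold change -4.58 ± 0.52, edgeR adjusted p = 0.0022). Mup3 fell by 3.13 and Elovl3, an elongase of very long fatty acids, by 4.50. Hsd3b5, a steroid dehydrogenase, had 7.72 ± 4.03 CPM in the DSS group; in the diet-alcohol group it had 7 counts, all in library 71. Its log2 fold change was -6.36, or -9.74 without library 71, and fitted values against a group near 0 are no bound on the fold. Outside the list, Mup21 had 0.946 ± 0.339 CPM in the diet-alcohol group (log2 fold change -6.08 ± 0.38, edgeR adjusted p = 3.4e-05). Mup genes are near-identical and their counts are uncertain singly; the call of Mup7 (log2 fold change -6.39) was lost without library 35 (edgeR adjusted p = 0.10) and that of Elovl3 without library 45 (0.051). Mup7 stood at -5.79 without DSS 48 and Elovl3 at -5.68 without library 71. Both calls were lost without a filter on low counts (0.077 and 0.114), and that of Hsd3b5 with limma-voom (0.105). The list median was -2.82 with the mitochondrial share as a covariate. Of 9 tested female-biased genes 1 rose, Cyp2b9, and 2 fell, Cyp2a4 and Cyp4a10, with 4 higher and 3 lower when adjusted over the list alone; the list was not called (median 0.70, camera adjusted p = 0.872). The Y-linked genes, 4 of them tested, had a median of -0.10 with none past either the test over all genes or that adjusted over the list alone.

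**Figure D4:**
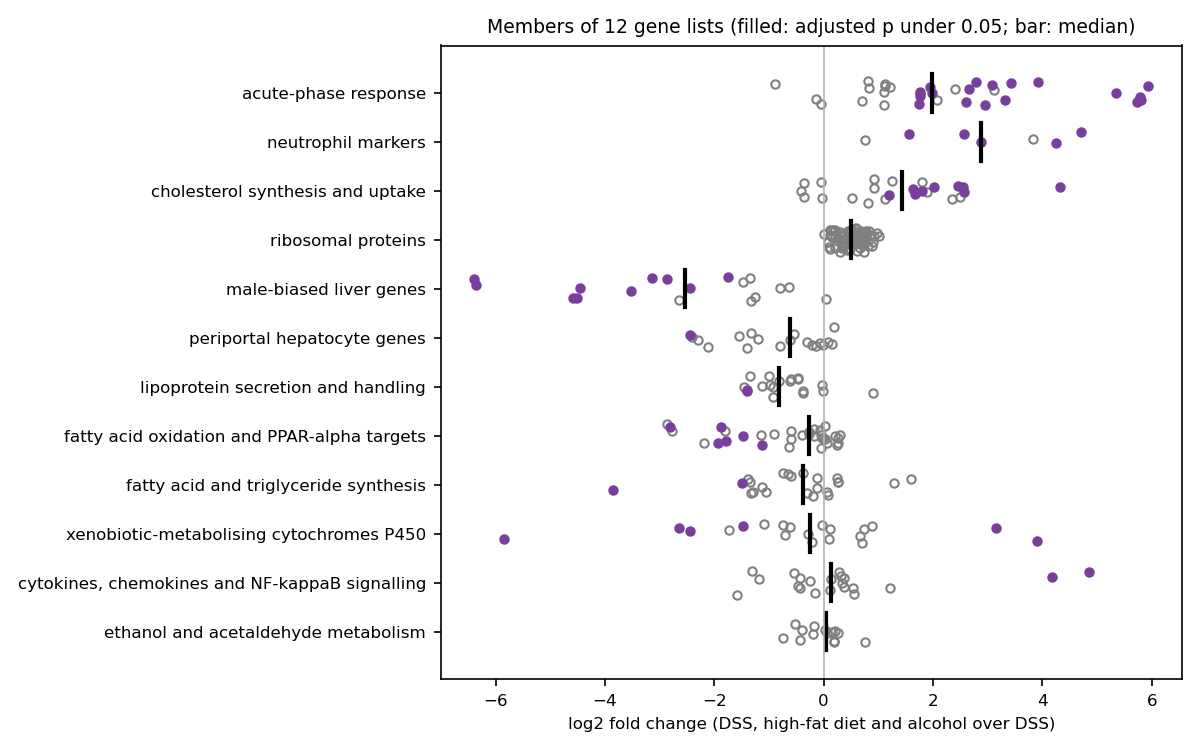
Log2 fold changes (diet-alcohol over DSS) of the tested members of 12 gene lists, with 1 point per gene, filled where the edgeR adjusted p was under 0.05, and a bar at each list's median. The medians run from -2.54 for male-biased genes to 2.88 for neutrophil markers.

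Xenobiotic-metabolising cytochromes P450 moved both ways: of 20 tested, 4 fell, among them Cyp3a11 and Cyp2f2, and 2 rose, Cyp2c39 and Cyp2b9. When adjusted over the list alone 7 were lower and 4 higher (median -0.25, camera adjusted p = 0.028; adjusted p = 0.436 with an estimated correlation). Cyp3a11, the main mouse counterpart of human CYP3A4, went from 309 ± 159 to 49.3 ± 13.2 CPM (log2 fold change -2.64 ± 0.44, edgeR adjusted p = 0.013). Cyp2f2 fell by 2.44, Cyp2a4, which is near-identical to Cyp2a5, by 5.84, and Cyp2c39 rose by 3.16. Cyp2a4 stood at -6.99 without library 65, Cyp2c39 at 3.78 without DSS 15 and Cyp2b9 at 2.99 without library 45. Leaving out DSS 48, 49 or 50 or diet-alcohol 65 or 71 ended the list's call (camera adjusted p up to 0.312), and its median was -0.50 without library 35, -0.42 without library 65, -0.48 without library 71 and -0.15 without DSS 48. The call of Cyp3a11 was lost without DSS 48 or diet-alcohol 45 (edgeR adjusted p up to 0.064), that of Cyp2a4 without DSS 50 or diet-alcohol 45 (up to 0.061), that of Cyp2c39 without DSS 48, 49 or 50 or diet-alcohol 45 (up to 0.092), and that of Cyp2b9 without any library but 71 (up to 0.153). The mitochondrial covariate ended the list's call (median -0.29, camera adjusted p = 0.364) and those of Cyp2a4, Cyp2f2, Cyp2c39, Cyp2b9 and Cyp3a11 (edgeR adjusted p = 0.062, 0.076, 0.113, 0.124 and 0.204), with Cyp2a4 at -4.95. With limma-voom Cyp2a4, Cyp2c39 and Cyp2b9 lost their calls (0.144, 0.225 and 0.444), and without a filter on low counts Cyp2b9 did (0.226). Of 29 genes of the glutathione and NRF2 list, Gstm2 rose (1.52) and Gsta4 fell (-2.32), and 27 did not pass; 1 was higher and 3 lower when adjusted over the list alone (median 0.17, mean 0.04, test direction down, camera adjusted p = 0.878; 0.028 without library 35). With the mitochondrial share as a covariate its median was -0.12 and it was called down (camera adjusted p = 0.047). The Gstm2 call was lost without DSS 48, 49 or 50 or diet-alcohol 45 (edgeR adjusted p up to 0.071) and with the same covariate (0.138). None of 14 genes of ethanol and acetaldehyde metabolism passed, also when adjusted over the list alone (camera adjusted p = 0.872). The median of that list was 0.04 (-0.20 without library 35) and its mean -0.04; Aldh2, the mitochondrial acetaldehyde dehydrogenase, stood at -0.53 (-0.28 without library 35) and Aldh1a7 at 0.76 (0.40 without library 35).

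Periportal hepatocyte genes had a median of -0.61 (camera adjusted p = 8.6e-08, and 0.189 with an estimated correlation), and of -0.92 with the mitochondrial covariate. Of 19 tested, 1 fell, Cyp2f2, which is also in the male-biased list, and 9 were lower when adjusted over the list alone. G6pc, glucose-6-phosphatase, had a log2 fold change of -1.55 (edgeR adjusted p = 0.092; -2.22 with the covariate) and Alb of -1.20 (0.115). None of 19 pericentral genes passed, with 3 higher and 4 lower when adjusted over the list alone (median -0.22, camera adjusted p = 0.466). Of 21 genes of gluconeogenesis and the fasting response 2 fell, both of glycogen metabolism: Ppp1r3b, a glycogen-targeting phosphatase subunit (-2.01), and Pygl, liver glycogen phosphorylase (-1.10). In that list 4 were lower when adjusted over the list alone (median -0.21, camera adjusted p = 0.013; adjusted p = 0.260 with an estimated correlation). Without library 65 the list was not called (median -0.08, camera adjusted p = 0.118); its median was -0.11 without DSS 48, -0.42 without library 71 and -0.53 with the mitochondrial covariate. Both gene calls were lost without DSS 48, 49 or 50 or diet-alcohol 45, 65 or 71 (edgeR adjusted p up to 0.163 and 0.137) and with that covariate (0.419 and 0.215), and that of Ppp1r3b also with limma-voom (0.066). None of 32 genes of amino acid catabolism and the urea cycle passed either adjustment, over all genes or over the list alone (median -0.17, camera adjusted p = 0.015; adjusted p = 0.609 with an estimated correlation). That list was not called without DSS 49 or diet-alcohol 35 or 65 (camera adjusted p up to 0.186), and its median was -0.06 without library 35, -0.36 without library 45 or 71 and -0.47 with the covariate. Otc and Ass1, of the urea cycle, stood at -0.91 and -0.79. Among 28 hepatocyte secreted proteins and identity factors C9, of the terminal complement pathway, fell by 1.11; 2 were higher and 4 lower when adjusted over the list alone (median -0.31, camera adjusted p = 0.048; adjusted p = 0.578 with an estimated correlation). That list was not called without DSS 48 or 49 or diet-alcohol 65 (camera adjusted p up to 0.333), with a median of -0.20 without DSS 49, and the C9 call was lost without any of the same 6 libraries as those of Ppp1r3b and Pygl (edgeR adjusted p up to 0.161) and with the covariate (0.138).

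All 77 tested ribosomal protein genes had positive fold changes, with none past the test over all genes or over the list alone (median 0.50, camera adjusted p = 4.2e-16; adjusted p = 0.230 with an estimated correlation). Rps13 and Rpl30 had log2 fold changes of 0.73 and 0.92. None of 88 nuclear-encoded genes of oxidative phosphorylation passed over all genes or when adjusted over the list alone (median -0.10, camera adjusted p = 0.312; called down with the mitochondrial share as a covariate, adjusted p = 0.023). The 13 mitochondrially encoded genes had a median of -0.90, with none past either adjustment, over all genes or over the list alone (camera adjusted p = 0.00081; adjusted p = 0.578 with an estimated correlation). The median was -0.36 without DSS 50 and -1.94 without diet-alcohol 65. It was 0.21 with the mitochondrial share as a covariate, and the list was then not called (camera adjusted p = 0.237). That share is computed from the counts of these same genes, so the loss of the call was bound to follow and carries no further information. Of 27 genes of the unfolded protein and integrated stress responses 1 rose, Asns, the asparagine synthetase gene (2.84 ± 0.58, edgeR adjusted p = 0.035; 3.75 without DSS 15), and 3 were higher when adjusted over the list alone (median 0.32, camera adjusted p = 0.012; adjusted p = 0.373 with an estimated correlation). The call of the list was lost without library 65 (camera adjusted p = 0.053) and that of Asns without DSS 48, 49 or 50 or diet-alcohol 45, 65 or 71 (edgeR adjusted p up to 0.167), with limma-voom (0.098) and with the covariate (0.151).

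Sinusoidal and vascular endothelial markers had a median of -0.44 (camera adjusted p = 0.0041; adjusted p = 0.578 with an estimated correlation), with none of 18 past the test and 3 lower when adjusted over the list alone. Dnase1l3 and Bmp2 had log2 fold changes of -1.75 and -1.26 (edgeR adjusted p = 0.118 and 0.116). The median was -0.68 without DSS 15, -0.67 without library 65, -0.17 without DSS 50, -0.27 without library 35 and -0.28 without library 71, which ended the call (camera adjusted p = 0.060). The mitochondrial covariate turned it to 0.12 and ended the call too (camera adjusted p = 0.833). None of 27 stellate cell and matrix genes passed either adjustment, over all genes or over the list alone (median -0.14, camera adjusted p = 0.872), with Pdgfra at 1.31 and Acta2 at 1.22 (0.59 and 0.33 without library 35). With the mitochondrial share as a covariate that list's median was 0.52 and it was called up (camera adjusted p = 0.0013). In the test without the covariate, none passed among 10 cholangiocyte markers (median 0.09, mean -0.09, camera adjusted p = 0.827), 14 cell cycle genes (median 0.11, camera adjusted p = 0.872; Ccnd1 at -0.80) and 20 genes of p53 targets and cell death (median -0.13, camera adjusted p = 0.817; Cdkn1a at -1.28, or -2.01 without library 45), nor did any when adjusted over the list alone. The cell cycle median was -0.30 with the covariate, and that list was not called (camera adjusted p = 0.633). Of 7 red blood cell genes, 18 genes of hypoxia and glycolysis and 18 immediate-early and heat-shock genes none passed, also when adjusted over the list alone. Their camera adjusted p-values were 0.760, 0.817 and 0.872 and their medians -0.08, 0.09 and -0.01, with the median opposite in sign to the test direction for red blood cell genes and to the mean for hypoxia. None of 16 circadian clock genes, 17 genes of arachidonic acid metabolism and 15 of retinol metabolism passed; 1, 1 and 4 were lower when adjusted over the list alone (medians 0.15, 0.17 and -0.16; camera adjusted p = 0.597, 0.676 and 0.074). Retinol metabolism was called without library 35 (camera adjusted p = 0.040). Of adipocyte genes, 2 were tested and Car3, a carbonic anhydrase that hepatocytes also express, fell by 4.43, also when adjusted over the list alone; its call was lost without library 35 (edgeR adjusted p = 0.054), with the covariate (adjusted p = 0.062) and without a filter on low counts (0.083), and it stood at -5.46 without library 71. Of pancreatic acinar genes 1 was tested, which passed only when adjusted over the list alone.

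The remaining genes with the largest changes lay outside the lists. Igdcc4, an immunoglobulin superfamily member, had a log2 fold change of 6.10 ± 0.78 (edgeR adjusted p = 0.0037), with 4 counts in all DSS libraries and 458 in the diet-alcohol libraries. It stood at 7.25 without DSS 15, and its call was lost with limma-voom (adjusted p = 0.233). Inmt, indolethylamine N-methyltransferase, went from 200.3 ± 23.3 to 13.7 ± 6.59 CPM (log2 fold change -3.88 ± 0.36, edgeR adjusted p = 0.00044). Cib3, a calcium-binding protein gene, fell by 5.61, from 11.7 ± 6.53 to 0.283 ± 0.356 CPM. It stood at -6.40 without library 65, and its call was lost with limma-voom (adjusted p = 0.177) and with the mitochondrial share as a covariate (-4.88, adjusted p = 0.062). Of 44 lists fixed before the data were examined, 40 were tested and 21 called with the preset correlation, 6 up and 15 down; 3 of the 21 held with an estimated correlation and 11 by fry, which called 12.

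In the authors' deposited table, 431 genes had an adjusted p under 0.05, of which 195 were higher and 236 lower in the diet-alcohol group. It shared 147 of its calls with the 148 genes of the edgeR test.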

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

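Of the tests in this part, those of depth, of genes at 0.3 to 1 CPM, of the hepatocyte share, of growth hormone targets, of residual blood, of Lrg1, of the split count for all changed genes and of splits by libraries exchanged were chosen only after the result was seen.

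A single library lay far from the other 3 of its group in 20 of 286 groups of values checked, where chance gives about 5%. This check takes each value singly, and over all genes library 35 lay farthest from the rest, at 154 on the first principal component against -33.7 to -6.13. Each is given with its gap to the nearest library as a share of the group's range, judged against Dixon's 95% critical value. Library 35 had 784 genes at 1 to 9 counts against 4375 to 4987 (0.854), the lowest lipoprotein list score (0.856) and the lowest Cyp2f2 (0.917). DSS 15 had the lowest periportal list score (0.895), the highest immediate-early list score (0.976), the highest Saa1 (0.841) and Rpl30 (0.860), and the lowest Lipc (0.831), Lyz2 (0.859) and Ugt1a9 (0.843). DSS 49 had the lowest Il1b (0.851) and Abcb4 (0.897) and the highest Cyp1a2 (0.838). Library 65 had the highest Kupffer list score (0.875), Cxcl1 (0.884), Slco1a1 (0.831) and Socs2 (0.988). Library 71 had the highest Hsd3b5 (1, the other 3 being at 0), Car3 (0.849) and Hba-a1 (0.861). Lyz2, Hba-a1, Abcb4 and Cyp1a2 come from the lists; Ugt1a9 and Socs2 were chosen after their values were seen.

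For the small number of low-count genes in library 35, the first pattern weighed, lower depth is argued against: libraries with fewer nuclear counts listed at least 5.51 times as many such genes. A filter on low counts as the only difference of library 35 is argued against by genes of 20 to 100 CPM. Their spread in library 35 was 1.57 times the largest of the other 3 (95% bootstrap interval 1.43 to 1.72). That interval reaches below the bound of 1.5 set beforehand. The reading rests on its lower end lying above 1, a criterion adopted after the result was seen. A wider spread at these levels cannot show whether low counts were removed as well, so such a filter stays open as a source of the missing low counts. Few distinct molecules behind the library stay open: genes of 0.3 to 1 CPM elsewhere, where listed, stood at 2.08 times their level, but the 63.2% at 0 alone allow 2.72, and removal of low counts would raise that ratio too. For genes of 1 to 5 CPM the ratio was 1.01, below the 1.5 set beforehand, which the 22.1% at 0 put out of reach (at most 1.28), and no biological explanation was tested.

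The second is the fall of male-biased genes. A lower share of hepatocytes is argued against by the hepatocyte list, whose median lay 2.23 above that of the male-biased list, and the mitochondrial share by a median of -2.82 with it as a covariate. Weaker growth hormone and STAT5 signalling is a candidate explanation: a set of 5 other targets (Egfr, Nudt7, Ghr, Igfals, Cish) was lower by 1.44 in mean score (a difference of -1.44, exact p = 0.0286, the smallest possible, which the 8.77% of tested genes without overlap between groups also reach), though only Igfals passed singly (-2.79), a call lost without DSS 48 (edgeR adjusted p = 0.051), without library 45 (0.051) and with the mitochondrial covariate (0.088). Outside the set, Igf1, of the gluconeogenesis and fasting list, stood at -0.99 without passing (edgeR adjusted p = 0.185), while Socs2 fell by 2.77 (edgeR adjusted p = 0.0076). The female-biased list was not called (camera adjusted p = 0.872). The set was listed after the pattern but before its own values were looked up. Mup1, Mup17 and Cyp4a12a were taken out afterwards because they belong to the list or the Mup family, so weaker signalling is a hypothesis only. Diet, alcohol and the acute-phase response were not told apart as sources.

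The third is the rise of neutrophil markers. Residual whole blood as the only source is argued against, since the neutrophil median lay 2.97 above that of red cell genes. The red cell value leans on DSS 15, whose list score was 1.66 against -1.03 to -0.52 in the other DSS libraries. The diet-alcohol scores were 0.03 to 0.45, above those of DSS 48, 49 and 50, so some residual blood is not excluded. Blood cells other than red cells are not excluded either: none of 6 platelet genes passed singly, yet all had positive values (median 1.46, camera adjusted p = 3.2e-05, and 0.189 with an estimated correlation). Lrg1, which hepatocytes also express, does not carry the list alone: 4 other members rose, of which Retnlg passed without each library in turn and S100a8 (edgeR adjusted p = 0.107 without DSS 48, log2 fold change 3.71 without DSS 15), S100a9 and Prtn3 did not. More cells of the neutrophil lineage stay open: the summed CPM of 12 low-count transcripts of the same list, left out by the filter, was 0.844 ± 0.565 and 3.59 ± 2.38 (SD, n = 4 each, exact two-sided permutation p = 0.0571). In library 35, which listed few low counts, the sum came from Mmp9 (36 counts) and Mmp8 (23 counts) alone. Library 71 (1.43 CPM) lay below DSS 15 (1.56 CPM).

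Of the 35 splits, 1, the real one, gave as many changed genes (148, highest other 0), as many higher (69, highest other 0), lower (79, highest other 0) and 2-fold changed genes (147, highest other 0). These counts come from 1 fit and are not separate tests, and 1 of 35 is the smallest share the splits allow. That share speaks against an arbitrary grouping only to that extent, and not against other differences that go with the groups. For gene lists 1 of 35 gave as many (21), but the highest other split gave 20 and the median of the others was 11.5. That other split exchanges DSS 15 for library 65 and so keeps part of the real contrast. The 16 splits that exchange 1 library per group gave 10 to 20 lists, and the 18 that exchange 2 gave 1 to 14 (median 9). Those 18 hold equal numbers of both groups on each side, so no net group difference gives their calls. Camera with the preset correlation thus called lists without a group difference, and its small p-values for the 21 lists overstate the evidence.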

How the results depend on the processing

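The fits without mitochondrial genes and with the mitochondrial share as a covariate were chosen only after the data were seen. All 148 genes kept their sign in every alternative that gave them a value. Named genes were followed singly in fewer fits: RLE, DESeq2, limma-voom, no filter, each library left out, and the fits without mitochondrial genes and with the mitochondrial share. Of 63 named genes past the threshold, 23 passed in all of these. Counts of genes changed stayed within 1.5 times of 148 under RLE, upper-quartile, limma-voom, the stricter filter, the non-robust fit, protein-coding genes, both FPKM fits, glmTreat and without mitochondrial genes (120 to 176).

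Changed, higher, lower and 2-fold changed genes numbered 431, 195, 236 and 387 with DESeq2 (431 by the authors' adjusted p), 320, 146, 174 and 319 without a filter, 684, 309, 375 and 498 with sample weights, and 55, 28, 27 and 55 with the mitochondrial covariate; the cause was not tested. An adjusted p threshold of 0.01 left 61, 29, 32 and 61, as a stricter threshold must. Leaving out 1 library gave 58 to 308 changed, 26 to 142 higher, 32 to 166 lower and 58 to 288 2-fold changed genes: 58 without DSS 48, 74 without DSS 49, 77 without DSS 50, 83 without library 45 and 308 without library 35. Fewer libraries lower the power, and the cause of the rise without library 35 was not tested.

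Gene lists called numbered 3 with an estimated correlation and 12 with fry (11 of them among the 21), which makes another comparison; leaving out 1 library gave 16 to 24. Among the 21 called lists the median reversed for B and plasma cell markers without library 45 (0.051, with -2.02 to 0.051 over the libraries left out). With the mitochondrial covariate it reversed for endothelial markers (0.12). It also did for mitochondrially encoded genes (0.21), whose own counts make up that covariate. Hba-a1 reversed without DSS 15 (0.63, with -1.30 to 0.63 over the libraries left out). Apart from the mitochondrially encoded genes, the cause was not tested. With the mitochondrial covariate 23 lists were called. Of the 21, 5 lost their call: MHC class II, B and plasma cell, endothelial, P450 and mitochondrially encoded genes, the last of which were bound to. With it 7 others gained a call, among them stellate cell (-0.14 to 0.52) and glutathione genes (0.17 to -0.12), whose medians changed sign. Of the 63 named genes 13 lost their call with limma-voom, 9 without a filter and 31 with the covariate, which also moved Elovl3, Hsd3b5 and Car3 further down by more than 1.5 times. The mitochondrial share had group means of 65.2% (DSS) and 45.2% (diet-alcohol), so the covariate overlaps the group contrast. Calls lost with it were not told apart from lower power. At this depth Tnf and Il6 were too scarce to test.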

Other observations

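All gene families and genes in this part, and their tests, were chosen only after the result was seen. Some called members are counted in the fixed lists too. Mt1, Mt2, Serpina3n and Serpina3m are in the acute-phase list, C6 in the Kupffer and male-biased lists, and C9 in the hepatocyte list.

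These families were picked because members stood among the changed genes, so they are given as counts without a test of the family. Of 13 tested carboxylesterases, which hydrolyse esters and drugs, 5 fell and 8 did not pass (median -1.81), among the 5 Ces3b (-2.49) and Ces3a (-2.38). Of 13 UDP-glucuronosyltransferases 4 fell and 9 did not pass (median -1.41), among them Ugt2a3 (-3.23) and Ugt1a9 (-2.56, whose call was lost without DSS 48 or 49, edgeR adjusted p up to 0.060). Of 21 complement components 3 fell, with Mbl2 at -2.40. Of 20 genes of zinc transport and metallothioneins, Mt1 (3.08) and Mt2 (3.32) rose and the zinc importer gene Slc39a4 fell (-1.64). The call of Mt1 was lost without DSS 48 or diet-alcohol 45 (edgeR adjusted p up to 0.092), and that of Mt2 without any library but DSS 50 and diet-alcohol 71 (up to 0.169), with limma-voom (0.074) and without a filter on low counts (0.245). The mitochondrial covariate ended the calls of Mbl2 (edgeR adjusted p = 0.055), Ces3a (0.061), Mt1 (0.077), Mt2 (0.129) and Ugt1a9 (0.163). Of 27 serpins 3 rose and 1 fell, and of 16 coagulation genes 1 fell. Dnajc12, a co-chaperone gene, rose by 2.99 ± 0.20 (edgeR adjusted p = 3.4e-05), and Socs2, a feedback inhibitor of growth hormone signalling, fell by 2.77 (edgeR adjusted p = 0.0076; -3.38 without library 65).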
